A study of Mus musculus with 18 samples.

How the data were processed

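The series profiled 2 histone marks in mouse embryonic stem cells of 3 genotypes: a Mettl3 Control, and the Mettl3 knockout lines KO1 and KO2. Mettl3 encodes the catalytic subunit of the enzyme that writes N6-methyladenosine (m6A) on RNA. H3K27ac marks active promoters and enhancers, and H3K4me3 marks promoters. Of the 18 samples, 12 are immunoprecipitated libraries with a peak list each, 2 per genotype and mark, and 6 are input chromatin, which were not analysed here. Per the labels, the cells have a C57BL/6 background and grew with LIF and inhibitors of GSK3 and MEK (CHIR99021 and PD0325901). Per the labels' protocols, formaldehyde-fixed chromatin was precipitated with a Diagenode automated kit in the presence of spike-in chromatin and its antibody from Active Motif, and libraries were made with a KAPA kit. Whether the spike-in or the input libraries entered the peak calling is not stated in the sources used here, but the scaling recovered below points to a control library. Nothing in the labels says that the replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

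Per the submitters' processing notes, the build was mm10 and the tools included CASAVA, Trimmomatic 0.38, Bowtie 1.2.2 and MACS2, whose version is not given in the sources used here. The authors called peaks on each immunoprecipitated library separately. In the deposited lists each peak carries the authors' fold enrichment (a ratio) over local background. The deposited lists also carry the authors' −log10 p and −log10 q of each peak, and every peak had a q under 0.01. A peak's fold or p belongs to its own list and was used here only within that list. Peaks of 1 list never overlapped, the shortest were 150 bp wide, and peak number and number of separate regions were therefore equal. Read totals are not given in the lists, so sequencing depth is unknown. A background level was recovered instead for each library from the authors' fold and p of each peak, by solving a Poisson tail for the pileup and the background, and the mean background of peaks on each autosome was divided by that of peaks on the other autosomes. This background moves with depth and also with fragment length. The recovery took either the immunoprecipitated or the control pileup as unscaled. It found immunoprecipitated pileups scaled by 0.647 to 0.934 in some libraries, which presumes a control library in the peak calling. On simulated lists 100% of peaks were solved and 100% of backgrounds found.

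Genes came from a GRCm38.p6 table, the assembly of mm10, with 49997 genes, gene starts and ends but no strand and no transcript starts. The 21894 genes used were the 21883 protein-coding ones and the other members of the gene lists on chromosomes 1 to 19, X and Y. The planned promoter window, 2 kb on each side of the transcription start, could not be placed without strand. The gene end with the more H3K4me3 was tried first in its place. On looking at where named genes fell (Mettl3 had no peak at either end, and the window of Esrrb lay at its far end), that window was replaced, before any limma model was fitted, by the 4001-bp window centred inside the gene, in steps of 100 bp, with the most H3K4me3, Control and knockout libraries having equal weight. H3K4me3 placed 15552 windows, of which 67.6% were centred within 1 kb of a gene end, H3K27ac placed 116, and 6226 genes without a peak of either mark were never tested. A window can lie on the start of a nested or neighbouring gene, so a gene's name says where the window lies and not which transcript it serves.

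Promoter coverage was the percent of the window covered by peaks. Genes entered a fit with a mean of at least 5% over the 6 libraries of a mark and values that were not identical in all of them. Distal H3K27ac was the length covered within 50 kb on each side of the window centre, leaving out bases within 2.5 kb of either end or the window centre of any protein-coding gene. It was analysed as log2(bp + 500) for genes with a mean of at least 1000 bp, so that fold changes of low values are understated. Neighbouring genes share such windows and are not independent. Each measure was fitted with limma (lmFit, and eBayes with a trend) over the 3 genotypes, with contrasts for the mean of KO1 and KO2 minus Control, for each line minus Control, and for KO2 minus KO1, at a Benjamini-Hochberg adjusted p of 0.05. Values given below for both lines together are from the first contrast, which a change in 1 line alone can bring past the threshold. Gene lists were compared with the other tested genes by camera with an inter-gene correlation of 0.01 where at least 8 members were tested, adjusted over the lists of a fit, and again with an estimated correlation. The estimated correlation was run only in the main fit of each measure, for both lines together. It cannot judge a list that passed only in another fit. A promoter was gained where a peak met the window centre within 1 kb, by at least 1 bp, in all 4 knockout libraries and in neither Control library, and lost in the reverse case. Counts of peaks were compared by 2-sided exact permutation of 2 Control against 4 knockout libraries (15 assignments, smallest possible p 0.0667). Similarity was the Jaccard index of covered bases.

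The 18 gene lists held 604 entries, all matched in the gene table: naive pluripotency, formative and primed pluripotency, mesoderm and endoderm, neuroectoderm, primitive endoderm, trophectoderm, 2-cell-like genes, Hox clusters, imprinted genes, germline genes silenced by promoter methylation, interferon and double-stranded RNA response, m6A machinery, chromatin regulators, p53 targets, glycolysis, ribosomal proteins, other housekeeping genes, and fibroblast (feeder) markers. Lists, tests, the first set of alternatives and the naming rule were fixed before the data were examined. The rule takes, per fit, the 6 protein-coding genes with the largest rise and the 6 with the largest fall among those called with every knockout library beyond both Control libraries (no symbols that start with Gm or end with Rik), up to 3 members per list by size of change, 4 gained and 4 lost promoters per mark, and 9 genes always (Mettl3, Mettl14, Pou5f1, Sox2, Nanog, Klf4, Esrrb, Gapdh and Actb). For length alone, and after values had been seen, list members were limited to the first 2 per promoter fit and the first 1 in the distal fit. Genes outside the rule are named only in the closing section, and a few that the rule takes are not reported here.

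Alternatives were peaks with −log10 q of at least 5, equal numbers of peaks per list (ranked by the authors' −log10 p), merging of peaks within 1 kb, windows of 1 kb (promoter) or 25 kb (distal) on each side, log2(bp + 100) for promoters, a pseudocount of 100 bp for distal windows, no filter on low coverage, quantile normalization, the replicate number as a block, leaving out each library, and, for gained and lost promoters, 500 bp covered or 2 kb on each side. Those chosen after seeing the data were fits without chromosomes 4, 6, 8, 11, 12 and 18, the gene-end window, the whole gene, fits of 1 knockout line with Control alone, and reruns of the overlap and similarity values. Where a library is left out and its genotype keeps 1, that library is assumed to vary like the others. On simulated data with 200 changed genes in each of 5 rounds, H3K27ac promoter fits (10187 genes) recovered 20.8% of changes of 10 percentage points and 98.2% of changes of 25. H3K4me3 promoter fits (14117 genes) recovered 10.0% and 90.8%. Distal fits (4382 genes) recovered 31.8% of changes of 0.5 and 89.2% of changes of 1 on the log2 scale. False calls were 6.5%, 5.3% and 4.5%. The simulated genes varied independently, without bounds and without a shift common to all genes, so these shares need not hold for the real fits. KO1 and KO2 calls share the Control libraries. Unchanged groups were simulated 50 times for the correlation and covariance of changes that this sharing alone brings. Such groups yield few or no calls, so they cannot judge the number of shared calls. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.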

Results

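The series asked how the m6A machinery bears on chromatin, by mapping H3K27ac and H3K4me3 in mouse embryonic stem cells of 3 genotypes: Mettl3 Control, KO1 and KO2. Each genotype and mark had 2 replicate libraries, 12 in all, each with its own peak list on mm10. Values by genotype below are means ± SD of these libraries (n = 2) unless another n is given. Coverage is in percent of the promoter window and differences of coverage are in percentage points. The number of reads behind a list is unknown. H3K27ac lists held 29973 and 32957 peaks in Control, 40210 and 39048 in KO1, and 65398 and 61383 in KO2. H3K4me3 lists held 83644 and 81608 peaks in Control, 69995 and 69320 in KO1, and 72303 and 66483 in KO2.

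Coverage at Mettl3, the targeted gene, is no readout of the deletion, because a promoter can keep its marks when a coding part is removed. In the Mettl3 window (mm10 chromosome 14, 52302941 to 52306941) H3K4me3 coverage was 65.4% and 68.4% in the Control libraries, 37.9% and 41.5% in KO1, and 48.0% and 44.1% in KO2. This was a fall of 24.0 points in both lines together (limma adjusted p = 0.0177), which lost its call after quantile normalization (14.3 points, 0.0808). H3K27ac coverage of the same window was 18.7% and 22.2% in Control, 20.9% and 19.8% in KO1, and 31.9% and 28.0% in KO2 (limma adjusted p = 0.174). Mettl14, which encodes the partner subunit of the methyltransferase, had H3K4me3 coverage of 71.2% ± 4.79 in Control, 45.2% ± 2.00 in KO1 and 45.2% ± 1.29 in KO2 (limma adjusted p = 0.0173; 0.0919 after quantile normalization).

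H3K27ac occupied more of the genome in the knockout lines, and far more in KO2. Peaks covered 14.5 Mb ± 0.186 in Control, 18.5 Mb ± 1.495 in KO1 and 36.2 Mb ± 1.10 in KO2, which is 1.28 times and 2.501 times the Control length. Covered length was also counted beyond 2.5 kb from the ends and window centres of protein-coding genes, which keeps the rest of gene bodies. It was 7.51 Mb ± 0.0433 in Control, 9.89 Mb ± 0.997 in KO1 and 19.6 Mb ± 0.907 in KO2. The number of protein-coding promoters with a peak was 7285 ± 267, 8504 ± 114 and 11165 ± 23.3, and the median peak width 327, 334 and 367 bp. Nearly all regions shared by both Control libraries met a peak in the knockouts (95.7% in KO1 and 97.9% in KO2). In contrast, 22451 of the 48523 regions shared by both KO2 libraries (46.3%), and 4740 of 28508 in KO1 (16.6%), met no Control peak. The mean number of peaks over all 4 knockout libraries was 1.64 times that of Control, 0.71 on the log2 scale, with every knockout library above both Control libraries. A 2-sided exact permutation over the 15 assignments gave p = 0.133, and the smallest it can give is 0.0667.

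H3K4me3 occupied less of the genome in the knockout lines. Peaks covered 57.3 Mb ± 1.31 in Control, 45.9 Mb ± 0.949 in KO1 and 45.9 Mb ± 5.91 in KO2. The difference lay mostly beyond 2.5 kb from the ends and window centres of protein-coding genes, which keeps the rest of gene bodies. The covered length there was 28.3 Mb ± 0.984 in Control, 19.96 Mb ± 0.662 in KO1 and 20.1 Mb ± 3.85 in KO2. The number of protein-coding promoters with a peak was 13699 ± 36.1, 13592 ± 10.6 and 13829 ± 182. Of the 60746 regions shared by both Control libraries, 18.1% met no KO1 peak and 22.2% no KO2 peak. The mean number of peaks over the knockout libraries was 0.841 times that of Control (log2 −0.25), lower in 4 of 4 libraries, at the smallest exact p the design allows, 0.0667. For promoters with a peak the ratio was 1.00 (exact p = 0.933). With peaks within 1 kb of each other merged, the log2 ratio of regions was −0.03 (exact p = 0.467).

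**Figure D1:**
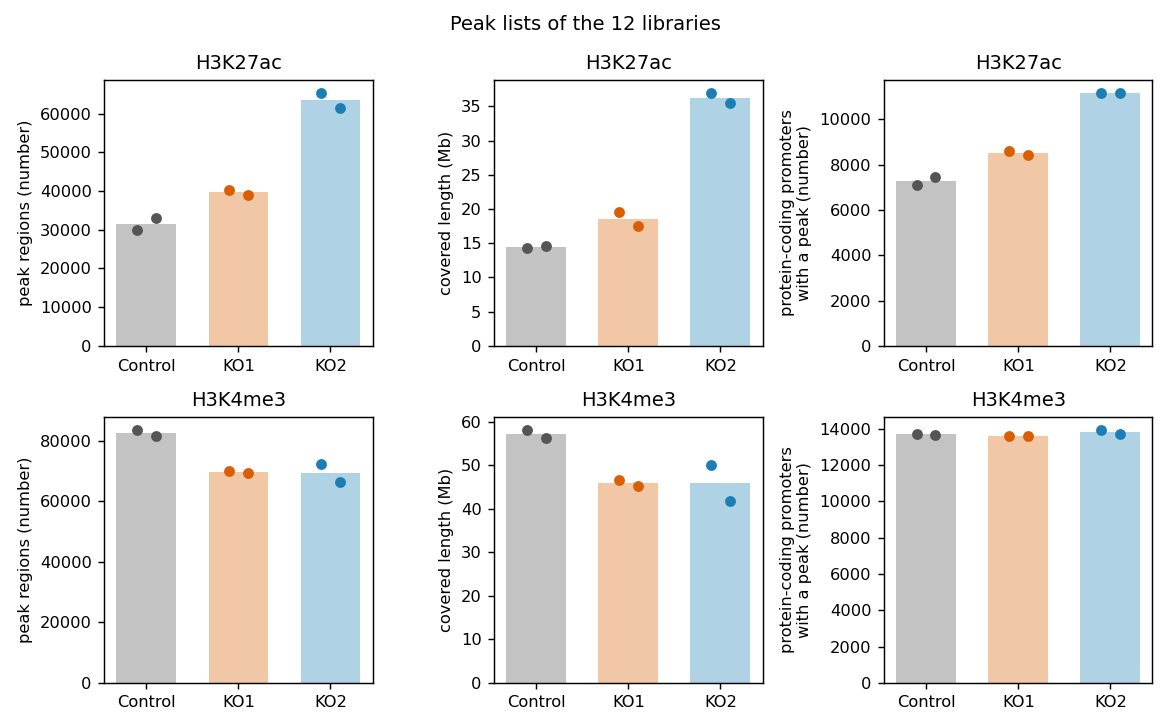
Number of peak regions, covered length in Mb and number of protein-coding promoters with a peak, by genotype, for H3K27ac (top) and H3K4me3 (bottom); points are libraries and bars are means of 2. H3K27ac regions run from 29973 to 32957 in Control and from 61383 to 65398 in KO2, and H3K4me3 regions from 81608 to 83644 in Control and from 66483 to 72303 in the knockout libraries.

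By the Jaccard index, replicates resembled each other more than libraries of different genotypes. The mean Jaccard index of covered bases was 0.581 ± 0.0409 within genotypes (n = 3 pairs) and 0.424 ± 0.0704 between them (n = 12 pairs) for H3K27ac, and 0.646 ± 0.00243 and 0.574 ± 0.0307 for H3K4me3. For both marks the pairing by genotype ranked first of the 15 ways to pair 6 libraries, a 1-sided exact p of 0.0667, which is the smallest possible. Unequal list lengths lower this index. By the percent of the shorter covered length that was shared, H3K27ac had 72.6%, 75.6% and 78.9% within Control, KO1 and KO2. Pairs of different genotypes had 72.3% to 90.7%. For H3K4me3 the values were 79.6%, 79.6% and 86.5% within and 76.5% to 83.3% between genotypes. By this share H3K27ac replicates were not more alike than other pairs, and the H3K4me3 ranges overlapped.

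The lines also differed in the background of whole chromosomes. Chromosome 8 had a relative background of 1.26 to 1.30 in the H3K27ac libraries of Control, against 0.970 to 0.986 in KO1 and 1.021 to 1.029 in KO2. Chromosome 11 was at 1.19 in both H3K27ac libraries of KO1, and chromosomes 4 and 12 were lowest there. Over the tested genes of chromosome 8, mean H3K4me3 promoter coverage was 4.72 and 4.85 points above that of the other autosomes in Control and between −0.987 and 0.383 in the 4 knockout libraries. The same difference for H3K27ac was 2.12 and 2.77 points in Control and −1.44 to −0.850 in the knockouts, each with an exact p of 0.0667. Named genes on chromosome 8 are marked as such below. On chromosomes 4 and 12, 14.7% and 10.9% of tested genes were lower in H3K4me3 promoter coverage (limma), against 9.02% of all tested genes. Lin28a and Meg3, named below, lie on chromosomes 4 and 12. Quantile normalization does not remove a difference between chromosomes.

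**Figure D2:**
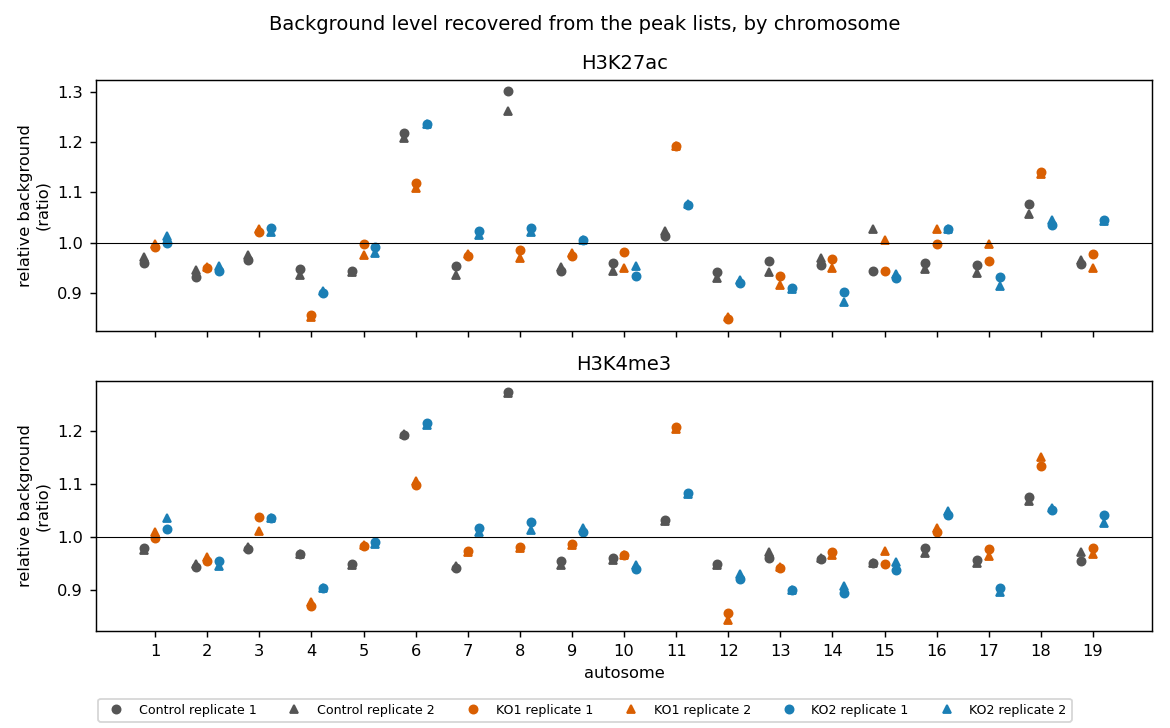
Relative background of each autosome (ratio of the mean background of its peaks to that of peaks on the other autosomes; the line marks 1), for H3K27ac (top) and H3K4me3 (bottom), 1 symbol per library. Chromosome 8 lies between 1.26 and 1.30 in all 4 Control libraries and near 1 in the knockout libraries, and chromosome 11 is highest in KO1.

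At promoters, H3K27ac coverage rose broadly in the knockouts. Of 10187 genes tested, 6403 (62.9%) were higher and 25 lower in the mean of KO1 and KO2 (limma, adjusted p under 0.05), with a median change of 10.3 points, 2.91 in KO1 and 17.5 in KO2. KO2 alone had 8777 higher and 24 lower and KO1 alone 56 higher and 5 lower, and KO2 was itself above KO1 at 7487 genes and below it at 20. Quantile normalization, which removes the shift common to all genes, left 251 higher and 109 lower. The gene with the largest rise was Pkd1l2, a polycystin family gene on chromosome 8 (117016179 to 117020179), from 7.34% ± 2.99 in Control to 69.3% ± 2.86 in KO1 and 89.1% ± 3.98 in KO2, which is 71.9 points ± 3.87 (SE) and 61.6 above the median shift (limma adjusted p = 0.00095). Pim3, a serine/threonine kinase gene (chromosome 15, 88862194 to 88866194), rose from 14.4% ± 2.67 to 63.4% ± 9.93 and 96.7% ± 1.06. Lyzl4, a lysozyme-like gene, rose from 4.87% ± 6.89 to 52.3% ± 1.41 and 85.9% ± 5.18. Dmtn, which encodes the actin-binding protein dematin, the forkhead gene Foxn3 and Hexa, which encodes a lysosomal hexosaminidase subunit, gained 57.7, 56.6 and 54.0 points. These 6 stayed past the threshold after quantile normalization.

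Falls were rare. Zmat4, a zinc-finger gene on chromosome 8 (24042726 to 24046726), dropped from 86.7% ± 6.34 in Control to 35.3% ± 3.66 in KO1 and 64.5% ± 15.9 in KO2, a change of −36.8 points ± 6.39 (SE; limma adjusted p = 0.00385). Klf12, a Krüppel-like factor gene, went from 47.5% ± 10.8 to 12.4% ± 4.47 and 32.2% ± 2.54. Ccdc141, the potassium channel gene Kcnt2 and the glypican gene Gpc3 changed by −24.98, −19.7 and −18.1 points. All 5 stayed lower after quantile normalization, and in the gene-end window Kcnt2 was higher instead and called so in limma (11.8 points). Calls for Gpc3 ended without Control replicate 1 or either KO2 replicate, and that for Kcnt2 without Control replicate 1.

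The core pluripotency genes carried more H3K27ac in KO2 than in Control. The Nanog window rose from 63.1% ± 8.68 to 76.3% ± 7.78 in KO1 and 96.2% ± 2.33 in KO2 (limma adjusted p for both lines = 0.00647) and that of Klf4 had 22.6% ± 2.60, 13.1% ± 9.40 and 71.3% ± 5.18 (0.0101). Pou5f1 (86.4%, 74.7% and 100.0%), Sox2 (80.7%, 77.4% and 98.6%) and Esrrb (35.5%, 16% and 72.7%) were not called for both lines together, and their differences turned negative after quantile normalization (−4.02, −0.48 and −9.14 points). In the contrast of KO2 alone all 3 were higher (limma adjusted p = 0.0135, 0.0195 and 0.00125). The reference genes moved too: Gapdh from 63.8% ± 5.85 to 72.8% ± 0.813 and 94.7% ± 0.619, and Actb from 40.1% ± 0.725 to 49.1% ± 0.336 and 67.3% ± 12.1. After quantile normalization the changes of Gapdh, Actb, Nanog and Klf4 kept their sign (6.07, 1.38, 10.1 and 2.81 points) and lost their calls. The call for Actb also ended without either Control or either KO1 replicate, and those for Nanog and Klf4 without Control replicate 1.

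Among the pluripotency and lineage lists, 24 of 40 naive pluripotency genes rose in H3K27ac (24 adjusted over the list alone; 2 higher and 1 lower after quantile normalization), led by Mycn (40.4% to 53.01% in KO1 and 93.7% in KO2) and Dppa4 (15.1% to 32.5% and 61.7%). Of the 17 formative and primed genes tested 14 rose (14 adjusted over the list alone; 4 after quantile normalization). Among them was Foxd3, a forkhead gene of the exit from naive pluripotency (10.9% ± 1.40 to 53.2% ± 11.2 and 60.4% ± 1.18). In the mesoderm and endoderm list 3 of 7 rose and 2 fell (3 and 2 adjusted over the list alone; 0 and 2 after quantile normalization). Nodal was at 26.0%, 27.3% and 75.3%, and Wnt3a was among those that fell. All 6 tested neuroectoderm genes rose (6 adjusted over the list alone; 1 after quantile normalization). They included the hedgehog effector Gli2 (39.5% to 75.0% and 96.8%) and the neuronal tubulin gene Tubb3 on chromosome 8 (5.12% to 8.998% and 53.2%). Primitive endoderm genes rose in 8 of 9 cases (8 adjusted over the list alone; 2 after quantile normalization). Sparc went from 31.6% to 56.7% and 93.2% and Apoe from 11.5% to 19.3% and 65.03%. Trophectoderm genes rose in 5 of 8 (5 adjusted over the list alone; 0 after quantile normalization). Tfap2c was at 0%, 6.04% and 28.7% and Fgfr2 at 0%, 14.03% and 20.2%. Of the 2 tested Hox genes both rose, Hoxc13 (0%, 2.24% and 23.4%) among them (2 adjusted over the list alone; 0 after quantile normalization), and no 2-cell-like gene had enough coverage to be tested. Leaving out Control replicate 1 or 2 ended the call for Fgfr2, as did leaving out KO2 replicate 2.

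Among the regulatory and metabolic lists, 28 of 45 chromatin regulators rose (32 adjusted over the list alone; 1 after quantile normalization). The first were the H3K27 demethylase genes Kdm6b (7.11% ± 10.1 to 19.2% ± 2.19 and 68.1% ± 4.79) and Kdm6a (28.0% ± 1.08 to 47.0% ± 0.919 and 68.9% ± 0.778). In the m6A machinery 18 of 27 rose (18 adjusted over the list alone; 1 after quantile normalization). The m6A reader gene Igf2bp2 was at 7.998%, 42.6% and 74.1% and the methyltransferase adaptor gene Wtap at 0%, 4.92% and 34.5%. Mettl14, at 4.17%, 2.17% and 26.9%, was called for both lines together, with KO2 above KO1 (limma adjusted p = 0.000497), and lost its call after quantile normalization or without either Control replicate. Imprinted genes rose in 10 of 16 (10 adjusted over the list alone; 3 after quantile normalization). Slc38a4 was at 1.96%, 4.72% and 73.2% and Snrpn at 27.1%, 43.7% and 79.4%. Interferon and double-stranded RNA response genes rose in 10 of 13 (11 adjusted over the list alone; 2 after quantile normalization). The RNA sensor gene Oas2 was at 7.94%, 18.97% and 71.0% and the antiviral gene Ifitm3 at 31.5%, 39.1% and 88.2%. Of 5 germline genes 1 rose, Hormad1 (0%, 0% and 24.9%; 1 adjusted over the list alone; 0 after quantile normalization), and Zfp42 on chromosome 8, also a naive pluripotency marker, was not called at 48.3%, 39.1% and 75.0%. Glycolysis genes rose in 15 of 23 (16 adjusted over the list alone; 1 after quantile normalization). The glucose transporter gene Slc2a3 was at 20.4%, 30.9% and 76.6% and Ldhb at 0%, 10.2% and 48.2%. The p53 targets rose in 15 of 22 (15 adjusted over the list alone; 0 after quantile normalization). The apoptosis genes were Bbc3 at 11.4%, 22.3% and 66.5% and Bax at 28.9%, 43.8% and 66.8%, both lost without Control replicate 1. Ribosomal protein genes rose in 33 of 54 (32 adjusted over the list alone; 0 higher and 1 lower after quantile normalization). Rpl32 was at 32.8%, 41.4% and 89.8% and Rpl36 at 18.3%, 23.3% and 70.2%. Other housekeeping genes rose in 17 of 29 (14 adjusted over the list alone; 0 higher and 1 lower after quantile normalization). Tuba1b was at 33.5%, 51.1% and 71.5% and Hsp90ab1 at 40.8%, 49.8% and 82.2%. Fibroblast markers, which feeder cells would carry, rose in 5 of 6 (5 adjusted over the list alone; 0 after quantile normalization). Ccn1 was at 12.6%, 23.9% and 52.95%, lost without either Control replicate or KO2 replicate 1, and Vim at 0%, 3.86% and 40.0%.

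Set against the other tested genes, none of the 12 H3K27ac lists with enough members differed in camera, with adjusted p from 0.152 (formative and primed, median change 16.1 points against 10.3) to 0.752 (p53 targets), and 1 list, the formative and primed genes, had an unadjusted p under 0.05. The formative and primed list did pass after quantile normalization (adjusted p = 0.0393) and without KO1 replicate 1 (0.0202) or KO1 replicate 2 (0.0261), and had adjusted p = 0.738 with an estimated correlation in the fit of all libraries. In a fit of KO1 with Control alone the ribosomal protein list was lower than the other genes (camera adjusted p = 2.21e-06 at the fixed correlation; 0.738 with an estimated correlation for both lines together), with a median change of −1.33 points in KO1 and 23.7 in KO2. With KO2 and Control alone the formative and naive lists were higher (0.0497 each at the fixed correlation, and 0.738 each with an estimated correlation for both lines together). For both lines together the ribosomal protein, formative and naive lists did not pass in camera at the fixed correlation either (adjusted p = 0.619, 0.152 and 0.619). The estimated correlation therefore does not judge the fits of 1 line. In the KO1 contrast of the fit of all libraries camera pointed lower for the naive list (unadjusted p = 0.0557). For the formative list it pointed higher there (0.0492). The mesoderm and endoderm list, too small for the test with 7 members, passed as lower once 8 or more were tested, without Control replicate 1 (0.000235), Control replicate 2 (0.00974), KO1 replicate 1 (0.000981) or KO1 replicate 2 (0.000556), and with no filter on low coverage (14 members, 8.10e-05), all at the fixed correlation. For the m6A, ribosomal protein and trophectoderm lists the median lay above that of the other genes (10.4, 11.5 and 12.6 points) while the test pointed lower. Over all genes, 2826 were higher and 7 lower without Control replicate 1, 3152 and 10 without Control replicate 2, and 16 were lower without KO1 replicate 2, against 25 with all libraries. Equal numbers of peaks per list gave 3274 higher and 42 lower. A fit of KO1 with Control alone gave 0 higher and 0 lower in limma, with 1623 and 161 at an unadjusted p under 0.05, and KO2 with Control alone gave 8615 and 24.

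Gained H3K27ac promoters numbered 553 and lost ones 1. The 4 gained genes with the largest change were Stard8 on X (0% in Control, 16.2% ± 0.194 in KO1 and 80.9% ± 1.06 in KO2), Atp1b1, a sodium pump subunit gene (12% ± 2.23, 29.0% ± 4.97 and 92.0% ± 1.11), Zzz3, a gene of the ATAC acetyltransferase complex (10.0% ± 2.47, 24.8% ± 9.61 and 87.7% ± 7.74) and the cell cycle kinase gene Cdk6 (10.9% ± 3.29, 45.6% ± 5.11 and 67.2% ± 7.02). The lost promoter was a window inside Wnt3a, a Wnt ligand gene (chromosome 11, 59281536 to 59285536; 20.01% ± 0.654, 8.21% ± 6.24 and 12.8% ± 2.47 over the whole window), whose lower call in limma (adjusted p = 0.0272) ended without Control replicate 1, Control replicate 2, KO1 replicate 2 or either KO2 replicate. Without strand or transcript starts, this window is not shown to be the promoter of Wnt3a itself. Against Control, KO1 alone gained 573 and lost 51, and KO2 alone gained 2640 and lost 7. The highest gained count among the other 14 ways to set 2 libraries against 4 was 122. Set apart in the same way, the KO2 libraries held 1339 promoters met in neither Control nor KO1, more than the 553, and 15 splits cannot give a share under 0.05. Fewer libraries make the conditions easier to meet: 917 were gained without Control replicate 1, 1133 without Control replicate 2, 898 without KO1 replicate 1 and 956 without KO1 replicate 2, and 15, 5, 3 and 4 were lost (2 and 4 without KO2 replicate 1 or 2).

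Distal H3K27ac rose at most genes with such signal. Of 4382 genes tested, 3409 were higher and 25 lower in the mean of KO1 and KO2 (limma). The median change was 0.82 on the log2 scale, 0.36 in KO1 and 1.28 in KO2. KO1 alone had 1447 higher and 74 lower, KO2 alone 3832 and 20, and KO2 exceeded KO1 at 3321 and lay below it at 33. Quantile normalization gave 827 higher and 936 lower. Nfam1, an immune receptor gene, had 0.214 kb ± 0.0495 of H3K27ac within 50 kb in Control (chromosome 15, 82957536 to 83057536), 2.25 kb ± 0.271 in KO1 and 13.0 kb ± 0.264 in KO2, a log2 change of 3.10 ± 0.15 (SE), or 2.27 above the median (limma adjusted p = 3.93e-06). Clasrp and the zinc-finger gene Zfp296, which share a region of chromosome 7, went from 0 kb to 1.66 and 6.13 kb and to 1.56 and 5.78 kb. Dab2ip, a Ras GTPase-activating gene, went from 0.075 kb to 2.02 and 6.71 kb, and Zfp706 and LOC115488529, which share a window on chromosome 15, from 0.242 kb to 3.65 and 6.63 kb. The largest fall was at Cemip, a hyaluronan-binding protein gene (chromosome 7, 83943657 to 84043657), from 2.47 kb ± 0.3797 to 0.197 kb ± 0.0658 and 0.536 kb ± 0.0969, a log2 change of −1.80 ± 0.22 (SE). Kcnt2 (1.85, 0.482 and 0.740 kb), Tmem232 (5.30, 1.38 and 3.83 kb), the mitochondrial dehydrogenase gene Acad9 (1.72, 1.29 and 0.215 kb), Tmem263 (2.19, 1.51 and 0.661 kb) and the arylamine acetyltransferase gene Nat1 on chromosome 8 (1.76, 0.950 and 0.852 kb) were also lower. These 12 kept direction and call after quantile normalization, and the call for Nat1 ended without Control replicate 1.

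Around the pluripotency genes, distal H3K27ac was 8.14 kb ± 0.0827 in Control, 9.99 kb ± 0.547 in KO1 and 14.2 kb ± 0.285 in KO2 for Pou5f1, 1.76, 2.66 and 10.6 kb for Sox2, 10.9, 13.7 and 26.6 kb for Nanog, 1.196, 1.66 and 2.53 kb for Klf4, and 21.9, 19.03 and 39.6 kb for Esrrb. All 5 were called higher in the mean of KO1 and KO2, as were Gapdh (0, 0.261 and 2.82 kb) and Actb (1.15, 1.14 and 5.04 kb). With KO1 and Control alone, Esrrb (log2 change −0.21) and Actb (−0.00787) were not higher. Quantile normalization turned Pou5f1 (−0.07) and Klf4 (−0.28) negative without a call, turned Esrrb to a lower call (−0.19, limma adjusted p = 0.0259), and left Gapdh (0.54) and Actb (0.04) positive without a call. Leaving out Control replicate 2 ended the calls for Klf4 and Esrrb.

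Distal H3K27ac rose in more members than not in every list fixed beforehand except the trophectoderm, germline and 2-cell-like ones, and none differed from the other genes in camera (adjusted p from 0.44 to 0.957 over 10 lists, and no list below an unadjusted p of 0.05). With no filter on low coverage the naive pluripotency and p53 lists passed as higher (0.0031 and 0.0474 at the fixed correlation; 0.904 each with an estimated correlation and the filter). With the filter neither passed at the fixed correlation, so the estimated one does not judge the unfiltered fit. The counts in this paragraph are the same adjusted over the list alone, and those in brackets are calls higher and lower after quantile normalization, which made some members of most lists lower. Naive pluripotency genes rose in 30 of 32 (7 and 6), led by the LIF receptor gene Lifr (1.82 kb ± 0.472, 4.98 kb ± 0.894 and 13.6 kb ± 1.010). Formative and primed genes rose in 9 of 10 (1 and 3), with Tcf15 at 2.29, 3.57 and 9.33 kb. Mesoderm and endoderm genes rose in 5 of 6 (1 and 2), with Nodal at 1.71, 3.05 and 7.44 kb, and neuroectoderm genes in 5 of 6 (1 and 1), with Neurog1 at 0.245, 1.07 and 2.42 kb. All 3 primitive endoderm genes rose (1 and 0), with Sparc at 1.59 kb ± 0.0191, 5.93 kb ± 0.827 and 17.6 kb ± 1.46, and 2 of 4 trophectoderm genes (1 and 0), with Tfap2a at 0.506, 1.04 and 2.15 kb, which quantile normalization brought to 0.00 and just below. Hox genes rose in 4 of 4 (0 and 0), with Hoxb7 at 1.16, 1.505 and 4.16 kb. Chromatin regulators rose in 19 of 22 (1 and 6), with Hdac1 at 0.733, 1.39 and 5.44 kb, and m6A genes in 7 of 9 (5 and 2), with Mettl16 at 0.514, 1.53 and 6.26 kb. Imprinted genes rose in 5 of 8 (2 and 3), with the growth restrainer Grb10 at 0.436, 2.01 and 5.91 kb, interferon response genes in 6 of 9 (1 and 3), with Irf1 at 0.272, 2.12 and 3.60 kb, and germline genes in 1 of 2 (1 and 1), Tdrd9 at 0, 0.405 and 2.62 kb. Glycolysis genes rose in 11 of 12 (1 and 1), with Ldhb at 0, 0.586 and 2.54 kb, p53 targets in 13 of 13 (2 and 0), with Trp53inp1 at 0.271, 1.31 and 2.36 kb, ribosomal protein genes in 21 of 23 (6 and 2), with Rpl38 at 0, 1.08 and 3.12 kb, other housekeeping genes in 14 of 17 (0 and 3), with Gusb at 0.835, 1.15 and 4.81 kb, and fibroblast markers in 4 of 5 (0 and 2), with Ccn1 at 0.379, 0.845 and 2.60 kb. Of the 3 tested 2-cell-like genes limma called 0 (0 and 2), and 0 had an unadjusted p under 0.05. Tdpoz1, at 1.11, 1.96 and 1.41 kb, turned to a log2 change of −0.53 after quantile normalization and passed as higher without Control replicate 1. For chromatin regulators, other housekeeping, formative and naive genes the median (0.52, 0.60, 0.67 and 0.66) lay below that of the other genes (0.82) while the test pointed higher. Fits of 1 line with Control alone called 950 higher and 52 lower for KO1 and 3827 and 20 for KO2, equal numbers of peaks per list gave 1676 and 65, and the count of lower genes was 6 without Control replicate 1.

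**Figure D3:**
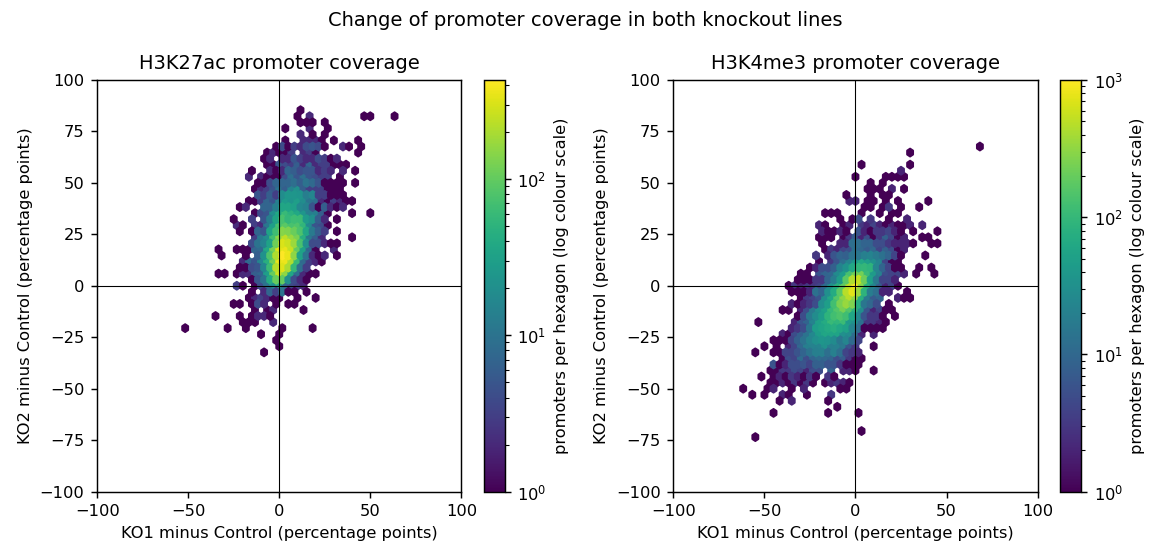
Change of promoter coverage in KO1 (horizontal) against that in KO2 (vertical), in percentage points, for the 10187 genes tested for H3K27ac (left) and the 14117 tested for H3K4me3 (right); colour gives the number of promoters per hexagon on a log scale. H3K27ac changes centre on 2.91 in KO1 and 17.5 in KO2, and H3K4me3 changes centre on −2.96 and −3.29.

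H3K4me3 coverage of promoters fell at more genes than it rose, by similar amounts in both lines. Of 14117 genes tested, 1274 were lower and 209 higher in the mean of KO1 and KO2 (limma). The median change was −3.16 points, −2.96 in KO1 and −3.29 in KO2. KO1 alone had 46 higher and 270 lower, KO2 alone 299 and 1409, and KO2 and KO1 differed at 89 genes higher and 52 lower in KO2. Quantile normalization gave 320 higher and 277 lower. Slc16a4, a monocarboxylate transporter family gene (chromosome 3, 107309530 to 107313530), fell most, from 78.7% ± 6.82 in Control to 22.4% ± 10.8 in KO1 and 4.24% ± 0.336 in KO2, a change of −65.4 points ± 4.85 (SE; limma adjusted p = 0.00723). Zmat4 (91.6% ± 0.442 to 28.3% ± 0.265 and 42.4% ± 15.8) and the adhesion scaffold gene Bcar1 (94.1% ± 4.86 to 36.6% ± 13.3 and 41.3% ± 6.61), both on chromosome 8, fell as well. Emb, which encodes the membrane protein embigin, the phospholipase gene Plcd3 and the fucosyltransferase gene Fut11 changed by −52.5, −49.8 and −48.1 points. Pkd1l2 on chromosome 8 rose most, from 15.3% ± 2.74 to 83.1% ± 2.07 and 81.6% ± 10.9, 67.1 points ± 5.37 (SE; limma adjusted p = 0.00723). Lyzl4 (1.88% ± 2.65 to 33.2% ± 15.1 and 66.7% ± 9.95), Cuedc1 (14.7% to 46.0% and 73.6%), the myelin gene Mobp (26.8% to 52.6% and 81.8%), the cadherin gene Fat2 (31.9% to 71.8% and 72.6%) and the interleukin-6 receptor gene Il6ra (9.30% to 34.6% and 64.0%) also rose. All 12 kept their calls after quantile normalization.

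These H3K4me3 calls are sensitive to single libraries. Without Control replicate 1, Control replicate 2, KO1 replicate 1 or KO1 replicate 2, limma called 0 genes higher and 0 lower, with 546 and 2239, 481 and 2497, 511 and 2899, and 572 and 2758 at an unadjusted p under 0.05, so that every H3K4me3 call named in this section ends there. The median change stayed between −3.43 and −2.95 in these fits, and KO2 with Control alone called 195 higher and 821 lower, 137 and 705 of them also called with all libraries. Without KO2 replicate 1 there were 103 higher and 1178 lower, and without KO2 replicate 2 there were 37 and 119. A window of 1 kb on each side gave 26 and 117, peaks with −log10 q of at least 5 gave 139 and 659, and dropping chromosomes 4, 6, 8, 11, 12 and 18 left 153 and 710. The gene-end window gave 129 and 531, of which only 81 and 407 were also called in the main window. In the gene-end window Il6ra (−0.57 points) and, of the genes below, Oas2 (−3.10), Ash2l (3.57), Psmd4 (2.57) and Tcf15 (1.51) had the opposite sign without a call.

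Pluripotency genes were split. The H3K4me3 windows of Pou5f1, Sox2, Nanog and Esrrb were covered over 100% of their length in all 6 libraries and could show no change, and those of Klf4 (95.7%, 94.8% and 97.6%), Gapdh (95.5%, 97.8% and 97.5%) and Actb (95.7%, 95.8% and 92.3%) were not called. Of 30 naive pluripotency genes tested 4 fell and 1 rose (4 and 1 adjusted over the list alone; 1 and 3 after quantile normalization). Lin28a, an RNA-binding protein gene (chromosome 4, 134009030 to 134013030), fell from 79.0% ± 3.38 to 33.8% ± 5.83 and 39.1% ± 2.49, and Stat3, the transcription factor of LIF signalling, from 95.4% ± 2.05 to 53.2% ± 15.2 and 63.0% ± 5.41. The fall of Lin28a stood after quantile normalization (−32.6 points, limma adjusted p = 0.0157) and that of Stat3 did not (−29.1, 0.0538).

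In the m6A machinery 6 of 26 genes fell and 1 rose (8 and 1 adjusted over the list alone; 1 and 1 after quantile normalization). Besides Mettl3 and Mettl14, the m6A reader gene Ythdf3 fell from 89.3% ± 4.37 to 64.5% ± 0.972 and 53.6% ± 7.74. Imprinted genes fell in 2 and rose in 2 of 30 (3 and 2 adjusted over the list alone; 1 and 2 after quantile normalization). The noncoding RNA gene Meg3 (chromosome 12, 109540096 to 109544096) fell from 70.2% ± 4.70 to 20.9% ± 4.95 and 16.3% ± 2.77, a change of −51.6 points ± 3.50 (SE; limma adjusted p = 0.00723), and Peg12 rose from 25.8% ± 7.05 to 44.0% ± 10.5 and 65.1% ± 0.495. In the germline list 2 of 12 rose (3 adjusted over the list alone; 1 after quantile normalization). Rpl10l, a testis ribosomal protein gene, went from 17.1% ± 3.52 to 58.1% ± 4.79 and 36.9% ± 4.74, and Tex19.1, not called, was at 36.9%, 55.3% and 52.7%. This list alone of 17 differed from the other genes in camera (higher, adjusted p = 0.0105, with a median change of 1.89 points and a mean of 4.59 against a median of −3.16), and adjusted p = 0.621 with an estimated correlation. It did not pass after quantile normalization, in windows of 1 kb on each side, without Control replicate 2 or without KO1 replicate 2. Without chromosomes 4, 6, 8, 11, 12 and 18 it had too few members to be tested. Without KO2 replicate 1, chromatin regulators (adjusted p = 0.00676) and ribosomal protein genes (0.0278) passed as lower too, and both had adjusted p = 0.923 with an estimated correlation in the fit of all libraries. In the fit of all libraries neither of these lists passed at the fixed correlation, so the estimated one does not judge the fit without KO2 replicate 1. Fibroblast and trophectoderm lists had medians (−5.16 and −4.32) below that of the other genes while the test pointed higher.

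Of 34 mesoderm and endoderm genes 5 fell (6 adjusted over the list alone; 4 after quantile normalization). Wnt3a went from 34.5% ± 6.96 to 5.22% ± 7.39 and 0%. Neuroectoderm genes fell in 2 of 33 (0 adjusted over the list alone, with 5 at an unadjusted p under 0.05 in limma; 0 after quantile normalization). They were Sox1 on chromosome 8 (72.2%, 44.2% and 56.4%) and Pax6 (32.1%, 16.7% and 4.37%). Of 21 primitive endoderm genes 3 fell and 1 rose (4 and 1 adjusted over the list alone; 1 and 0 after quantile normalization). Lama1 at 71.1%, 42.8% and 46.5% and Fst at 69.5%, 50.5% and 46.4% were among those that fell. The median change of the list was 0.0687 points and the mean −2.96. Trophectoderm genes fell in 1 and rose in 1 of 17 (1 and 1 adjusted over the list alone; 0 and 1 after quantile normalization). Esx1 on X rose from 10.6% to 31.7% and 33.1%, and Tfap2a, not called, was at 67.1%, 53.7% and 42.0%. Formative and primed genes fell in 1 of 25 (0 adjusted over the list alone, with 4 at an unadjusted p under 0.05 in limma; 0 lower and 1 higher after quantile normalization), Tcf15 (68.6%, 39.0% and 59.9%), and Sall2 was not called at 46.9%, 28.6% and 33.2%. Limma called 0 of 31 Hox genes, with 2 lower at an unadjusted p under 0.05. Hoxd11 (21.7%, 9.47% and 13.9%) and Hoxc9 (21.5%, 16.3% and 9.41%) had the largest differences.

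Chromatin regulators fell in 5 of 43 (5 adjusted over the list alone; 2 lower and 1 higher after quantile normalization). The H3K9 methyltransferase gene Suv39h2 was at 72.8%, 55.3% and 45.8% and Ash2l on chromosome 8, which encodes a core subunit of H3K4 methyltransferase complexes, at 98.6% ± 1.98, 87.9% ± 6.79 and 69.6% ± 5.09. Other housekeeping genes fell in 2 of 29 (2 adjusted over the list alone; 0 lower and 1 higher after quantile normalization), Psmd4 (76.4%, 57.8% and 43.7%) and Snrpd3 (95.3%, 82.6% and 64.3%). Ribosomal protein genes fell in 1 of 53 (0 adjusted over the list alone, with 9 at an unadjusted p under 0.05 in limma; 0 after quantile normalization), Rpl11 (95.6%, 76.4% and 74.8%), and Rpl8 was not called at 92.6%, 80.3% and 72.4%. The p53 targets fell in 1 of 24 (0 adjusted over the list alone, with 4 at an unadjusted p under 0.05 in limma; 0 lower and 1 higher after quantile normalization), the death receptor gene Tnfrsf10b (68.8%, 47.6% and 34.7%), and Btg2 was not called at 72.9%, 54.5% and 61.6%. Interferon response genes rose in 2 of 21 (2 adjusted over the list alone; 2 after quantile normalization), Oas2 (28.4%, 32.8% and 65.6%) and Oas1a (26.9%, 42.9% and 46.2%). Among fibroblast markers 1 of 14 rose (1 adjusted over the list alone; 0 after quantile normalization), and Ccn2 was not called at 76.6%, 55.7% and 51.3%. Limma called 0 of 23 glycolysis genes, with 1 higher and 5 lower at an unadjusted p under 0.05 and 2 higher after quantile normalization. Ldhb (46.9%, 57.6% and 87.7%) and Pdk1 (89.4%, 85.8% and 54.7%) had the largest differences. The calls of Suv39h2, Psmd4, Snrpd3, Rpl11, Tnfrsf10b, Tcf15, Pax6, Sox1, Lama1, and Fst ended after quantile normalization, each with an unchanged sign.

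Gained H3K4me3 promoters numbered 41 and lost ones 47. The 4 largest gains were at Ablim1, an actin-binding LIM gene (0%, 16.2% ± 1.86 and 53.9% ± 13.8), Apol6 (0%, 36.3% ± 7.55 and 23.1% ± 7.51), the securin gene Pttg1 (11.3% ± 3.71, 35.4% ± 1.96 and 37.7% ± 9.05) and the calcium pump gene Atp2b4 (6.35% ± 3.32, 11.8% ± 1.13 and 48.7% ± 13.7). The 4 largest losses were at Il12rb2, an interleukin-12 receptor gene (49.1% ± 5.73, 1.88% ± 2.65 and 2.55% ± 3.60), Wnt3a, the epidermal gene Rptn (28.9% ± 0.159, then 0% in all 4 knockout libraries) and Atxn7l3b (42.0% ± 1.64, 15.7% ± 1.202 and 17.0% ± 0.866). Other splits of the 6 libraries gave up to 46 gained (KO1 set against the rest) and up to 71 lost (KO2 set against the rest), and 15 splits cannot give a share under 0.05. Gained counts were 129 without Control replicate 1, 114 without Control replicate 2, 67 without KO1 replicate 2 and 64 without KO2 replicate 2, and lost counts 106 without Control replicate 1 and 113 without Control replicate 2.

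Calls shared by KO1 and KO2 were counted last, since both contrasts use the same Control libraries. For H3K4me3, 201 genes were lower and 27 higher in both lines, where independent lists would share 26.9 and 1.0. Unchanged groups simulated against shared controls shared 0 and 0. That 0, here and below, follows from the setup, since unchanged groups yield few or no calls in either line. It is no reference for the shared calls. The changes correlated across genes at r = 0.684 (0.4999 simulated), with a covariance of 68.6 against 10.6 simulated. For H3K27ac promoters 56 genes were higher in both, all of the KO1 calls, against 48.2 for independent lists and 0 simulated, and 3 lower. Across settings the 56 ranged from 0 in windows of 1 kb on each side or with no filter on low coverage to 687 on the log2 scale and 1129 over the whole gene, and the 201 H3K4me3 falls from 0 to 1308 in the first and last of these windows. The H3K27ac promoter changes had r = 0.431 (0.5005 simulated) and a covariance of 33.8 against 8.64. In the distal fit 1413 were higher in both (1265.4 for independent lists, 0 simulated) and 3 lower, with r = 0.586 (0.5008 simulated) and a covariance of 0.24 against 0.0259. Genes are not independent replicates, and 2 Control libraries cannot be split, so part of the excess may come from the shared controls. For both promoter fits, leaving out any 1 library ended every shared call (0 in limma), and for the distal fit 616 shared rises were left without KO1 replicate 1, 848 without KO2 replicate 1 and 855 without KO2 replicate 2. Shared distal falls numbered 1 without either Control replicate and 6 without KO1 replicate 1.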

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

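The tests of KO2 against KO1 were planned; among the tests of causes, those of the 6 chromosomes, of immunoprecipitation strength for either mark, of depth in 3 H3K4me3 libraries and of chromosome 8 promoters were chosen only after the result was seen. What drew attention here was a difference between the knockout lines in the limma contrast of KO2 minus KO1, and groups of 2 allow no test for an outlying library. H3K27ac promoter coverage was higher in KO2 than in KO1 at 7487 genes and lower at 20, and distal H3K27ac was higher at 3321 and lower at 33. H3K4me3 promoter coverage was higher in KO2 at 89 and lower at 52.

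Among the named genes, H3K27ac promoter coverage differed between KO2 and KO1, in percentage points, at Slc38a4 68.5, Stard8 64.7, Atp1b1 63.0, Zzz3 62.9, Klf4 58.2, Esrrb 56.7 and Oas2 52.1. It differed at Ifitm3 by 49.1, Kdm6b 48.9, Rpl32 48.3, Nodal 48.0, Rpl36 46.9, Apoe 45.7, Slc2a3 45.7, Bbc3 44.2, Tubb3 44.2 and Mycn 40.7. Then came Ldhb 38.0, Sparc 36.5, Vim 36.1, Zfp42 35.9, Snrpn 35.7, Lyzl4 33.6, Pim3 33.3, Hsp90ab1 32.4 and Igf2bp2 31.4. Smaller differences stood at Wtap 29.6, Dppa4 29.2, Zmat4 29.2, Ccn1 29.0, Dmtn 27.1, Pou5f1 25.3, Hormad1 24.9, Mettl14 24.8, Foxn3 23.8, Bax 23.0, Tfap2c 22.7, Hexa 22.3, Gapdh 21.9, Gli2 21.9, Kdm6a 21.9, Cdk6 21.5, Sox2 21.3, Hoxc13 21.2 and Tuba1b 20.3. The smallest were Nanog 19.9, Klf12 19.8, Pkd1l2 19.8, Actb 18.2 and Mettl3 9.62.

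Distal H3K27ac differed between KO2 and KO1, on the log2 scale, at Nfam1 2.30, Gapdh 2.14, Sox2 1.83, Tdrd9 1.81, Actb 1.76, Mettl16 1.75, Gusb 1.71, Hdac1 1.66, Clasrp 1.62, Zfp296 1.60, Ldhb 1.57, Dab2ip 1.52 and Sparc 1.5. It differed at Grb10 by 1.40, Lifr 1.37, Tcf15 1.28, Ccn1 1.26, Hoxb7 1.22, Rpl38 1.22, Tmem232 1.19, Nodal 1.17 and Esrrb 1.04. Smaller differences stood at Nanog 0.94, Neurog1 0.89, LOC115488529 0.80, Zfp706 0.80, Tfap2a 0.78 and Pou5f1 0.49, and KO2 was below KO1 at Acad9 (−1.33) and Tmem263 (−0.80). For H3K4me3 promoter coverage the differences were 37.6 points at Ablim1, 36.9 at Atp2b4 and 27.6 at Cuedc1.

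More H3K27ac peaks and promoter coverage in KO1 and KO2 was the first pattern weighed. Greater depth as its whole cause is argued against, since the highest recovered background of a knockout library, 1.994, lay below the 2.16 of Control replicate 1, which had the fewest peaks (2.44 and 3.34 before the caller's scaling), while Control replicate 2, at 1.67, lay below 3 of the 4, so a part of depth stays open. Copy number of chromosomes 4, 6, 8, 11, 12 and 18 is argued against as the cause, since 66.59% of tested promoters were higher without them, against 62.85% with them. Stronger enrichment in the knockout immunoprecipitations cannot be told apart from a gain of the mark: with equal numbers of peaks per list 294 promoters were gained and 12 lost, and both predict this. An effect of Mettl3 loss stays open too, untested, and would have to be larger in KO2 than in KO1.

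Fewer H3K4me3 peaks in KO1 and KO2 was the second pattern, and lower depth in all 4 knockout libraries is argued against, since KO2 replicate 1 had a recovered background of 1.942, above the 1.737 of Control replicate 2 (2.08 and 1.737 before the caller's scaling). For the other 3 libraries lower depth may contribute, as their highest background, 1.611, was below both Control libraries. Weaker enrichment cannot be told apart from a loss of the mark, since both predict a fall beyond 2.5 kb from gene ends and window centres. The largest covered length there in a knockout library was 22.81 Mb, against 27.61 Mb in the lower Control library. The authors' median fold per list, 5.61 to 6.28 in the knockout and 5.21 and 5.35 in the Control libraries, runs against weaker enrichment, but lists of different lengths and backgrounds make it no measure of enrichment, so this stays open. An effect of Mettl3 loss stays open too, untested.

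Whole-chromosome differences between the lines were the third pattern. The peak share of chromosomes 4 and 8 and their relative background in KO1 lay on the same side of Control, with no overlap, in 4 of 4 comparisons, which fits a different copy number of these chromosomes. Only chromosomes 4 and 8 in KO1 were scored, and they were picked because their shares differed. Chromosomes 11 and 12 in KO1 also had share and background on the same side of Control for both marks. Chromosome 6 in KO2 did not for H3K27ac. Its background was 1.236 and 1.237, against 1.218 and 1.209 in Control, but its share was 5.89% and 6.01%, against 6.77% and 6.88%. Extra copies of chromosome 8 in Control would raise promoter coverage there, and in 8 of 8 knockout libraries the chromosome 8 difference lay below both Control libraries. Falls on chromosome 8, such as those of Zmat4, Bcar1, Ash2l and Sox1, go the way that extra copies of chromosome 8 in Control would turn them, and the rise of Pkd1l2 there goes against it. The H3K4me3 falls of these 4 genes were larger than the mean shift of the chromosome (−5.07 points), so their direction alone does not account for their size. No genomic read counts were analysed here, and an effect of Mettl3 loss on chromosome number was not tested.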

How the results depend on the processing

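Tests chosen only after the result was seen were the fits without 6 chromosomes (4, 6, 8, 11, 12 and 18), the gene-end window, the whole gene, the fits of 1 line with Control alone, and all reruns of the KO1 and KO2 overlap and of library similarity. Depth limits every value here: reads per list are unknown, 2 libraries per genotype cannot bring an exact p below 0.0667, a window covered in full cannot show a rise, and a peak list cannot tell a weaker mark from a weaker immunoprecipitation. The highest coverage over all transcript starts of a gene, chosen beforehand as another measure, was not run, because no transcript starts were at hand. For the peak number, equal numbers of peaks per list fix the result at no difference by construction. An estimated correlation was run only in the main fits, so its values below do not judge lists that passed only under another setting. For every value below that moved, the cause was not tested, except that the fits of 1 line and the fits without 1 library have fewer libraries by construction.

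Peak numbers and similarity kept their direction throughout: without 1 library the log2 ratio of H3K27ac regions ran from 0.58 to 0.82 and that of H3K4me3 regions from −0.27 to −0.23, and similarity within minus between genotypes from 0.11 to 0.197 for H3K27ac and from 0.0609 to 0.0819 for H3K4me3. Without 1 library in turn, H3K27ac promoter genes higher ran from 2826 to 5449 and lower from 7 to 24, lists that differ from 0 to 2, H3K4me3 promoter genes higher from 0 to 103 and lower from 0 to 1178, lists from 0 to 3, and distal genes higher from 2703 to 3581 and lower from 6 to 35, lists from 0 to 0. Calls shared by KO1 and KO2 ran from 0 to 0 for both promoter fits and both directions, and from 616 to 1254 (higher) and 1 to 6 (lower) for distal genes. Promoters gained ran from 559 to 1133 for H3K27ac and 46 to 129 for H3K4me3, and lost from 2 to 15 and 60 to 113.

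With quantile normalization, H3K27ac promoter genes were 251 higher and 109 lower, with 28 and 7 shared calls. The 1 list that differed there was the formative and primed one, higher (camera adjusted p = 0.0393, and 0.738 with an estimated correlation in the main fit). H3K4me3 promoter genes were 320 higher and 277 lower, with 0 lists and 56 and 39 shared calls, and distal genes 827 and 936, with 279 and 200 shared. With equal numbers of peaks per list the H3K27ac promoter counts were 3274 and 42, the H3K4me3 lower count 836 and the distal counts 1676 and 65. Gained and lost promoters there were 294 and 12 for H3K27ac and 63 and 29 for H3K4me3. The stricter peak threshold gave 139 and 659 H3K4me3 promoter genes, 15 distal genes lower and 5 lost H3K27ac promoters. Windows of 1 kb on each side gave 12 H3K27ac genes lower and 26 and 117 H3K4me3 genes, with 0 lists, windows of 25 kb gave 1731 and 12 distal genes, and the log2 scale gave 15 H3K27ac genes lower. With no filter on low coverage 1 H3K27ac list was called, mesoderm and endoderm genes lower (too few members for the test with the filter), as were 5754 and 60 distal genes and 2 distal lists, naive pluripotency and p53 target genes higher (adjusted p = 0.904 each with an estimated correlation in the main fit), and with an estimated correlation 0 H3K4me3 lists. Requiring 500 bp gave 2 lost H3K27ac and 69 gained H3K4me3 promoters, and 2 kb on each side 0 lost H3K27ac promoters.

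Without the 6 chromosomes there were 710 H3K4me3 genes lower, 0 H3K4me3 lists and 0 lost H3K27ac promoters, and the germline list, the only one called with them, had too few members there to be tested. The gene-end window gave 8 H3K27ac genes lower, and 129 and 531 H3K4me3 genes. Its 1 H3K27ac list was the formative and primed one, higher (camera adjusted p = 0.0269, and 0.738 with an estimated correlation in the main window). The whole gene gave 414 and 2897 H3K4me3 genes and 3 lists, chromatin regulators and m6A machinery lower and germline higher (adjusted p = 0.923, 0.923 and 0.621 with an estimated correlation in the main window). KO1 with Control alone gave 0 and 0 H3K27ac promoter genes in limma (1623 and 161 at an unadjusted p under 0.05), 60 and 339 H3K4me3 genes, and 950 and 52 distal genes. It also gave 1 H3K27ac list, ribosomal protein genes lower (camera adjusted p = 0.738 with an estimated correlation in the fit of all libraries). KO2 with Control alone gave 2 H3K27ac lists, formative and naive genes higher (adjusted p = 0.738 each with an estimated correlation in the fit of all libraries), 821 H3K4me3 genes lower and 2 lists, chromatin regulators lower and germline higher (0.923 and 0.621).

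The replicate numbers did not pair the libraries (correlations of deviations from −0.0536 to 0.0355). With a replicate block there were 6300 and 27 H3K27ac promoter genes, 204 and 1195 H3K4me3 genes and 3429 and 28 distal genes. Shared calls there were 36 for H3K27ac higher, and 14 and 85 for H3K4me3 higher and lower. The block left the log2 ratios of regions at 0.71 and −0.25, with exact p = 0.222 and 0.111.

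Shared calls of KO1 and KO2 in the other settings were, higher and lower, as follows. For H3K27ac promoters, 1 and 0 with the stricter peak threshold, 1 and 0 with equal numbers of peaks, 0 and 0 in windows of 1 kb and with no filter, 687 and 1 on the log2 scale, 31 and 0 in the gene-end window and 1129 and 3 over the whole gene. For H3K4me3, 21 and 76 with the stricter threshold, 27 and 118 with equal numbers of peaks, 0 and 0 in windows of 1 kb, 14 and 23 on the log2 scale, 20 and 148 with no filter, 14 and 67 without the 6 chromosomes, 41 and 114 in the gene-end window and 137 and 1308 over the whole gene. For distal genes, 930 and 1 with the stricter threshold, 361 and 7 with equal numbers of peaks, 591 and 2 in windows of 25 kb and 738 and 10 with no filter. The cause was not tested.

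Named genes turned as follows, and the cause was not tested. Distal H3K27ac with quantile normalization was −0.19 at Esrrb, −0.28 at Klf4, −0.0685 at Pou5f1, −0.53 at Tdpoz1 and −0.00373 at Tfap2a, and with KO1 and Control alone −0.00787 at Actb and −0.21 at Esrrb. H3K27ac promoter coverage with quantile normalization was −9.14 at Esrrb, −7.28 at Mettl3, −4.02 at Pou5f1, −0.482 at Sox2 and −8.94 at Zfp42. With KO1 and Control alone it was −19.5 at Esrrb, −9.56 at Klf4, −2.0 at Mettl14, −0.075 at Mettl3, −11.7 at Pou5f1, −3.32 at Sox2 and −9.20 at Zfp42. Pou5f1 was also −0.369 with equal numbers of peaks, −2.20 in windows of 1 kb, −0.000113 on the log2 scale and −1.28 without KO1 replicate 1 (up to 3.20 without KO1 replicate 2), and Esrrb −0.0341 on the log2 scale. The gene-end window gave Kcnt2 11.8 and Zfp42 −0.181. H3K4me3 coverage of Actb was 3.85 with quantile normalization, 0.412 without Control replicate 2 (down to −3.59 without Control replicate 1) and 0.163 with KO1 and Control alone. In the gene-end window Ash2l was 3.57, Il6ra −0.575, Klf4 −1.76, Oas2 −3.10, Psmd4 2.57 and Tcf15 1.51. Klf4 was −0.000805 over the whole gene and −0.825 with KO1 and Control alone, and Hoxd11 0.450 in windows of 1 kb. Of the other values of named genes, 825 H3K27ac promoter, 607 H3K4me3 and 486 distal values kept direction and call, 122, 322 and 32 lost a call, and 8, 18 and 1 gained one.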

Other observations

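The tests in this part, of genes called for both marks, of the centre and flanks of promoter windows and of genes on the sex chromosomes, were chosen only after the result was seen. Genes here that were not named before lie outside the naming rule. Of 9938 genes tested for both promoter marks, 14 fell in both, among them Bnc2, Ccdc141, Hcrtr2, Hhla1, Kcnt2, Marchf8, Ncam2, Nfu1, Slc38a7, St6galnac3, Unc5d, Wnt3a and Zmat4, where independent calls would share 2.90. Slc38a7, Unc5d and Zmat4 lie on chromosome 8, where H3K27ac and H3K4me3 coverage relative to the other autosomes were both lower in the knockouts (−3.51 and −5.07 points; 2-sided exact p = 0.0667 each), so independence is no fair reference for them. Both marks rose at 163 genes (108 if independent), H3K27ac rose and H3K4me3 fell at 535 (727 if independent), and 0 had the reverse in limma (0.43 if independent). Pkd1l2 and Lyzl4 were among those that rose in both. The H3K4me3 calls among these end without any 1 of the Control or KO1 libraries.

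H3K4me3 coverage of the 4 tested genes on Y was higher in KO1 than in Control (limma). A different copy number of Y between the cell lines, such as loss of Y in Control cells, would give the same and was not tested. The rises on Y are therefore not read as a gain of either mark. On X, 24 of 428 genes rose in H3K4me3 and 14 fell, with a median change of 0.57 points. There 232 of 271 (85.6%) rose in H3K27ac, against 62.9% of all tested genes. The share of H3K27ac regions on X was 1.61% and 1.56% in Control, 2.10% and 2.01% in KO1 and 2.19% and 2.26% in KO2. A different copy number of X was not tested either, since relative background was computed for autosomes alone.

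The H3K4me3 difference was larger at the flanks of promoters than at their centre. Mean coverage of the inner 2 kb was 59.2% ± 0.400 in Control, 56.4% ± 0.379 in KO1 and 56.2% ± 3.02 in KO2 (2-sided exact p = 0.133), and that of the outer part 37.3% ± 0.516, 31.5% ± 0.439 and 30.1% ± 2.84 (0.0667, the smallest possible). The fall was larger in the outer part in 4 of 4 knockout libraries. Windows were centred where H3K4me3 was highest, so their centre is the part nearest to full coverage, and this count decides nothing about H3K4me3 coverage at the flanks of the promoter window. H3K27ac was higher in both parts, at 21.1%, 25.8% and 46.7% in the inner 2 kb and 12.8%, 15.1% and 26.7% in the outer part (exact p = 0.133 for each).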
